A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

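RNA levels of yeast genes were measured by RNA sequencing in 9 libraries, 3 of wild type (WT) and 3 of each double deletion strain. Per the labels' protocols, total RNA was taken from prototrophic CEN.PK cells in log phase, polyadenylated RNA was selected with oligo(dT), and cDNA was made with random primers. Each library's group and replicate number were taken from its title. The genotype labels of replicates 2 and 3 carry running digits in the gene names (pct2, pct3, ept2, ept3), which were read as replicate numbers, and the series' design text names PAH1 and DGK1, so the expression of all these genes was checked first.

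The authors deposited a table with a raw count and an FPKM value per gene and library. The authors' count values are whole numbers with a different total in each library, and HISAT2 2.2.1, HTSeq 0.6.1 and genome build R64 are named, with no role or order, per the submitters' processing notes. Whether the counting used strand, and how it treated reads with several matches, is not given in the sources used here. The FPKM values, so named per the file headers, equal the count divided by the exonic gene length in kilobases and by the library total, which was checked on 64098 values, of which 100% lay within 0.0051 or a relative 0.002. The table held 7122 genes and 6 further columns of 3 libraries with no matching sample, which were not analysed here. In 4 lines the values were removed before the table was used here; they hold at most 0.0158% of the total that FPKM implies for any library. Of the gene identifiers 6045 (84.88%) were found in the RefSeq annotation of build R64, and 6033 of these (99.80%) had the same start and end.

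The total counts ranged from 5669951 to 11793688 per library, the 10 highest genes took 9.86 to 10.6% of the counts, and TMM factors lay between 0.981 and 1.02. Within groups the log2 CPM of libraries correlated across genes with Pearson's r of 0.991 to 0.994, and their counts differed by more than sampling noise in every pair (chi-square per gene of 2.34 to 9.22), so no library was taken as a repeat of another. A principal component analysis without the deleted genes gave 23.0% and 17.3% of the variance to its leading components. PC1, the larger of these, did not separate the groups: WT replicate 3 (13.0) and ect1Δ pct1Δ replicate 2 (7.33) stood apart from the other libraries of their groups. PC2 set the ect1Δ pct1Δ libraries (-5.69, -6.54 and -6.43) apart from all others (-1.27 to 12.3).

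Before the data were examined, the design was fixed as limma on log2 FPKM if the table held FPKM alone and edgeR on counts if it also held counts. Since it held counts, genes were tested with edgeR 4.0.16 in R 4.3.3, with the quasi-likelihood functions glmQLFit and glmQLFTest, TMM normalisation and the filterByExpr filter by group. That filter removed 1039 genes and left 6083. All 9 libraries entered 1 fit with a mean per group and no covariates, with a biological coefficient of variation of 6.24% and 11.4 prior degrees of freedom. The comparisons were each double deletion against WT and cpt1Δ ept1Δ against ect1Δ pct1Δ, the last of which tests the difference between the strains. P-values are two-sided, adjusted by Benjamini and Hochberg over the genes tested, and called below 0.05. The SE of a log2 fold change is its size divided by the square root of the F statistic. Levels of deleted genes as a percentage of WT carry exact binomial (Clopper-Pearson) 95% intervals from the summed counts.

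Gene lists for 43 pathways, regulons and markers of other cell states, with 924 entries, were also fixed before the data were examined. Of the entries 923 matched a gene, and 1 list had fewer than 3 measured genes, which left 42 lists. Each was tested with limma 3.58.1's camera with a preset correlation of 0.01 between genes, adjusted over the 42 lists, with the deleted genes left out, and again with an estimated correlation and with fry. Members were also adjusted over the list alone.

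Genes were named by a rule fixed before the data were examined. It takes the deleted genes, PAH1, DGK1 and the remaining genes of phosphatidylethanolamine and phosphatidylcholine synthesis with their regulators. From each comparison with WT it takes the 6 largest positive and the 6 largest negative changes among called genes whose libraries do not overlap and which have a symbol other than the systematic name, with 4 each way between the strains. From each of up to 6 called lists with the smallest p it takes up to 3 members with the smallest adjusted p in the list's direction. From marker lists and from the lists for methionine and sulfur, methyltransferases and Ino2/Ino4 targets, where not called, it takes 1 called member. The rule gave 73 genes. The exceptions, chosen after their values were seen, are YBR242W, YDL057W, YGR201C, YDR133C, YNL134C and RDN5-1, the neighbours of these or of the deleted loci, the genes that lie next to the ARR genes, IMD1, TDH2 and YFR056C, which share sequence or position with named genes, and SCR1. EEB1 is named by the rule for cpt1Δ ept1Δ and is also given for ect1Δ pct1Δ. The plot of called genes shows every called gene, named by the rule or not.

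The test was tried on simulated counts drawn from the WT means and from the dispersions and library sizes of all 9 libraries, with 200 genes changed by known folds. So many changed genes raise the unadjusted p at which Benjamini-Hochberg adjustment calls a gene. The shares recovered are therefore likely higher than in the real comparisons. For ect1Δ pct1Δ against WT (6057 genes) it recovered 38.8%, 80%, 84% and 98% of genes changed 1.25-fold, 1.5-fold, 2-fold and 4-fold, and 2.60% of its calls were false. For cpt1Δ ept1Δ against WT (6067 genes) the shares were 59.2%, 76.0%, 91.8% and 100%, with 11.0% false calls, above the 5% aimed at, and between the strains (6064 genes) 50.0%, 86.0%, 96.0% and 98.0%, with 5.17% false calls. A list shifted by a log2 of 0.15 (oxidative phosphorylation) was recovered in each comparison, though 0 of its members were called singly, and 0 other lists were called in error, with the tricarboxylic acid cycle, which shares genes with it, left out of that count. Each gene was drawn independently, without correlation between genes. The trial therefore cannot show how often camera calls lists in error in the real libraries.

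The alternatives tried were limma on log2 FPKM with a pseudocount of 0.1 or 5, or of 1 without a trend, no filter on low counts, an FPKM of at least 10 in 3 libraries, centring on the median, only the 6 libraries compared, the replicate number as a block, a fold of at least 2, DESeq2 1.42.0 with its size factors, and each library left out in turn. Those chosen after the data were seen are limma with a pseudocount of 1 and a trend, total counts without TMM factors, a correction for exonic length and GC content (known for 100% of tested genes), lists without the genes next to deleted loci, and shared calls among genes with a mean of at least 20 CPM. Genes with a near-identical copy were sought with blastn 2.17.0 in the RefSeq sequence of build R64, at 90% identity or more over at least 100 bases. Chance overlap of calls against a shared WT group was estimated from 100 simulations of unchanged groups. In these all 9 libraries, WT included, were drawn anew from the mean of each gene.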

Results

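Polyadenylated RNA was sequenced from Saccharomyces cerevisiae of the CEN.PK background, a prototrophic laboratory yeast, in log phase in minimal medium with 2% glucose. The 9 libraries fall into 3 groups of 3: wild type (WT), a strain labelled as lacking ECT1 and PCT1 (ect1Δ pct1Δ) and a strain labelled as lacking CPT1 and EPT1 (cpt1Δ ept1Δ). ECT1 and PCT1 encode the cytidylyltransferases that make CDP-ethanolamine and CDP-choline. EPT1 and CPT1 encode the transferases that join these compounds to diacylglycerol, so the strains lack successive steps of the same route to phosphatidylethanolamine and phosphatidylcholine. The total counts were 10948488, 6271188 and 6141426 in WT replicates 1, 2 and 3, then 6338900, 11793688 and 5669951 in ect1Δ pct1Δ, and 8354262, 11245082 and 11429517 in cpt1Δ ept1Δ. Nothing in the labels says that the replicates of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. With 3 libraries against 3, an exact permutation test of a single value cannot give a two-sided p below 0.1, so the tests of genes come from edgeR's model fitted across all genes. Gene positions are those of build R64, and levels are CPM, counts scaled to the size of the library, unless FPKM is named.

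The deleted genes were nearly silent in the strains labelled as lacking them and at WT level elsewhere. ECT1 (YGR007W, chromosome VII, 506969 to 507940) stood at 110 ± 5.15 FPKM in WT (mean ± SD, n = 3 here and below), 0.167 ± 0.16 in ect1Δ pct1Δ and 109 ± 0.765 in cpt1Δ ept1Δ. PCT1 (YGR202C, chromosome VII, 903474 to 904748) stood at 107 ± 4.01, 0.720 ± 0.0265 and 105.3 ± 4.71 FPKM in the same order. CPT1 (YNL130C, chromosome XIV, 379558 to 380831) stood at 195 ± 5.56 FPKM in WT, 187 ± 5.34 in ect1Δ pct1Δ and 0.270 ± 0.208 in cpt1Δ ept1Δ. EPT1 (YHR123W, chromosome VIII, 354815 to 356081) stood at 128 ± 8.75, 128 ± 6.98 and 0.163 ± 0.217 FPKM. The 3 ect1Δ pct1Δ libraries together held 3 counts of ECT1 and 22 of PCT1, or 0.118% of the WT level (95% exact binomial interval 0.0243 to 0.345%) and 0.675% (0.423 to 1.02%). The 3 cpt1Δ ept1Δ libraries held 9 counts of CPT1 and 5 of EPT1, or 0.126% (0.0577 to 0.240%) and 0.107% (0.0348 to 0.25%). These intervals cover counting error only. PAH1, the phosphatidate phosphatase gene, and DGK1, the diacylglycerol kinase gene, which the series' design text names as the deleted genes, were expressed in all 9 libraries. PAH1 (YMR165C) stood at 20.9 ± 1.67, 18.9 ± 2.11 and 20.7 ± 1.66 FPKM in WT, ect1Δ pct1Δ and cpt1Δ ept1Δ, and DGK1 (YOR311C) at 123 ± 4.82, 123 ± 4.87 and 127 ± 0.885.

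**Figure D1:**
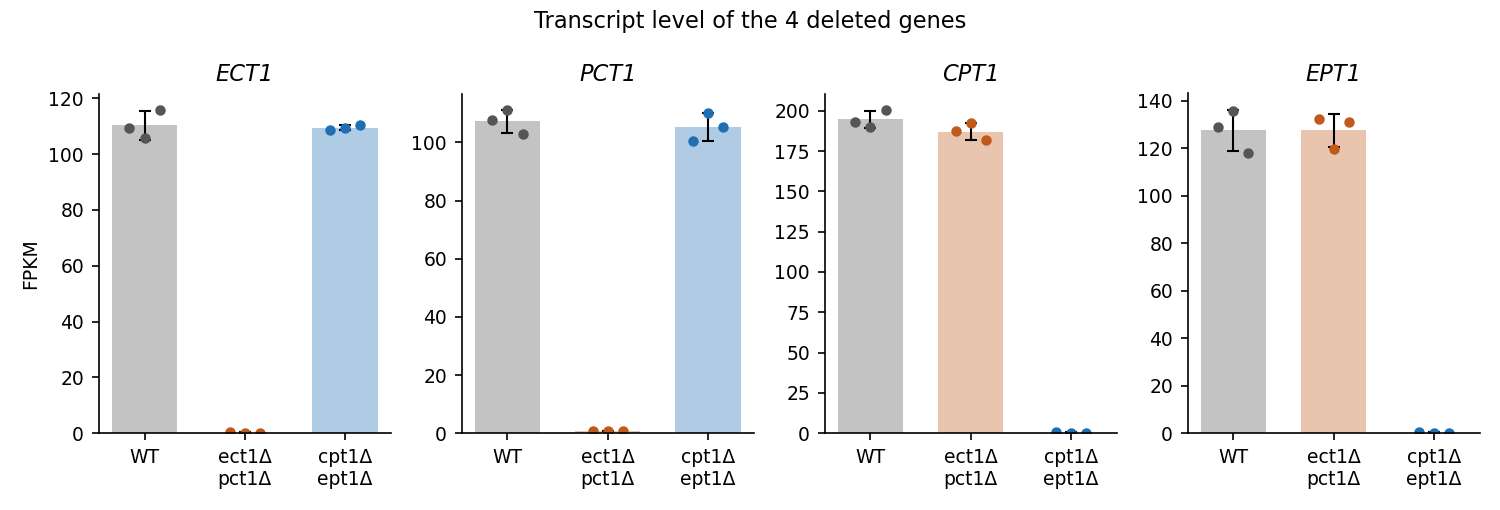
Mean FPKM of ECT1, PCT1, CPT1 and EPT1 in each group, with bars for means, error bars for SD and points for the 3 libraries of a group. Each gene is near 0 in the strain labelled as lacking it, with means of 0.167, 0.720, 0.270 and 0.163 FPKM, and near the WT level in the other groups.

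The comparison of ect1Δ pct1Δ with WT asks which transcripts differ once both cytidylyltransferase genes are missing. A few genes changed strongly, and they were not genes of phospholipid synthesis. The arsenic resistance genes, which lie side by side near the right end of chromosome XVI, were lower: ARR3, the arsenite exporter, fell to 13.0% of WT, ARR2, the arsenate reductase, to 20.6%, and ARR1, the activator of the other two, to 65.9%. ZRT1, the high-affinity zinc transporter, fell to 54.2% of WT, from 83.2 ± 4.24 to 44.7 ± 2.56 CPM. IMD2, an inosine monophosphate dehydrogenase of guanine nucleotide synthesis, rose 1.73-fold, from 89.6 ± 2.19 to 155 ± 2.44 CPM, and EEB1, an acyltransferase that makes ethyl esters of medium-chain fatty acids, rose 1.47-fold. STF2 and YGR201C, the genes directly beside the deleted ECT1 and PCT1, rose 1.74-fold and 3.22-fold.

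Of 6083 genes tested with edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment, 28 passed an adjusted p of 0.05, the 2 deleted genes included. Of the 26 others, 16 were higher and 10 lower in ect1Δ pct1Δ, 6 differed by at least 2-fold and 12 by less than 1.5-fold. In all 26 the libraries of ect1Δ pct1Δ did not overlap those of WT, which held for 10.6% of all tested genes and holds for 10% by chance. An unadjusted p below 0.05 was reached by 402 genes, against 304 expected by chance, and 98.2% of the tested genes lay within 1.5-fold of WT.

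By the same edgeR test with Benjamini-Hochberg adjustment, ARR3 (YPR201W, 939922 to 941136) had a log2 fold change of -2.94 ± 0.32 (SE) and an adjusted p of 2.98e-05, from only 4 to 8 counts per ect1Δ pct1Δ library against 32 to 69 in WT. ARR2 (YPR200C, 939279 to 939671) changed by -2.28 ± 0.48 with 0 to 16 counts against 31 to 34, and its edgeR Benjamini-Hochberg adjusted p was 0.0381. ARR1 (YPR199C, 938148 to 939032) changed by -0.60 ± 0.10, with 135 to 293 counts against 227 to 384. Other genes with a symbol had edgeR log2 fold changes of -0.88 ± 0.13 for ZRT1 (YGL255W, chromosome VII, 20978 to 22108), 0.80 ± 0.09 for STF2 (YGR008C, chromosome VII, 508110 to 508364), 0.79 ± 0.06 for IMD2 (YHR216W, chromosome VIII, 554396 to 555967) and 0.56 ± 0.07 for EEB1 (YPL095C, chromosome XVI, 368071 to 369441). Their edgeR Benjamini-Hochberg adjusted p-values were 0.00121, 2.90e-05, 1.74e-07 and 8.60e-05. Rises were also found for YRO2, FMP48, HSP30, a stress-induced plasma membrane protein, TDH1, a glyceraldehyde-3-phosphate dehydrogenase, and YGP1, a secreted glycoprotein, with log2 fold changes of 0.66, 0.66, 0.64, 0.61 and 0.55. PDR5, a drug exporter, URA1, the dihydroorotate dehydrogenase of pyrimidine synthesis, and KAR2, the main Hsp70 chaperone of the endoplasmic reticulum, fell by 0.32, 0.27 and 0.26 on the log2 scale. IMD2 is 96.3% identical over 1576 bases to IMD1 and TDH1 is 90.2% identical over 999 bases to TDH2, so reads of these pairs can be exchanged and their values are uncertain. The calls of YRO2, PDR5, URA1, YGP1, KAR2 and ARR2 ended when any of 3 to 5 single libraries was left out (edgeR, Benjamini-Hochberg adjusted p up to 0.229), and each library except cpt1Δ ept1Δ replicate 1 ended at least 1 of them. Limma on FPKM without a trend ended these calls too, and those of FMP48, HSP30, TDH1 and ZRT1 (Benjamini-Hochberg adjusted p of 0.0903, 0.0739, 0.215 and 0.190). Over all alternatives with every library the values reached 0.390 for YRO2, 0.315 for ARR2, 0.402 for PDR5, 0.357 for YGP1 and 0.190 for URA1 (limma, Benjamini-Hochberg adjusted p). Without WT replicate 1 the total was 17 genes in place of 28.

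Some of the strongest changes were in genes known only by an identifier, named here after their values were seen. YBR242W (chromosome II, 704670 to 705386) fell from 85.6 ± 3.86 to 28.1 ± 2.90 CPM, a log2 fold change of -1.63 ± 0.08 with an edgeR Benjamini-Hochberg adjusted p of 4.52e-10. YDL057W (chromosome IV, 351434 to 352420) rose 3.57-fold, from 5.86 ± 1.5 to 21.1 ± 1.47 CPM, and its edgeR Benjamini-Hochberg adjusted p was 1.36e-06. YGR201C (chromosome VII, 902520 to 903197) rose from 13.7 ± 3.12 to 42.8 ± 4.30 CPM, with an edgeR Benjamini-Hochberg adjusted p of 1.15e-06. RDN5-1, a 5S ribosomal RNA gene with identical copies elsewhere in the genome, had a log2 fold change of -1.29 ± 0.19 in these poly(A) libraries. Nuclear ribosomal RNA genes together took 10.1 to 13.6 CPM in WT, 4.26 to 5.0 in ect1Δ pct1Δ and 7.30 to 8.84 in cpt1Δ ept1Δ. Nearly all of this was RDN5-1 itself, at 9.97 to 13.3, 4.20 to 4.90 and 7.08 to 8.77 TMM-scaled CPM. The sum is thus no separate evidence of a group difference in ribosomal RNA. Whether the RDN5-1 call reflects a difference in RNA or poly(A) selection between the groups cannot be told from these data. The genes on either side of YBR242W (VVS1 and ALG7, log2 fold changes of -0.07 and -0.10) and of YDL057W (USO1 and MBP1, -0.04 and -0.15) were not called.

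**Figure D2:**
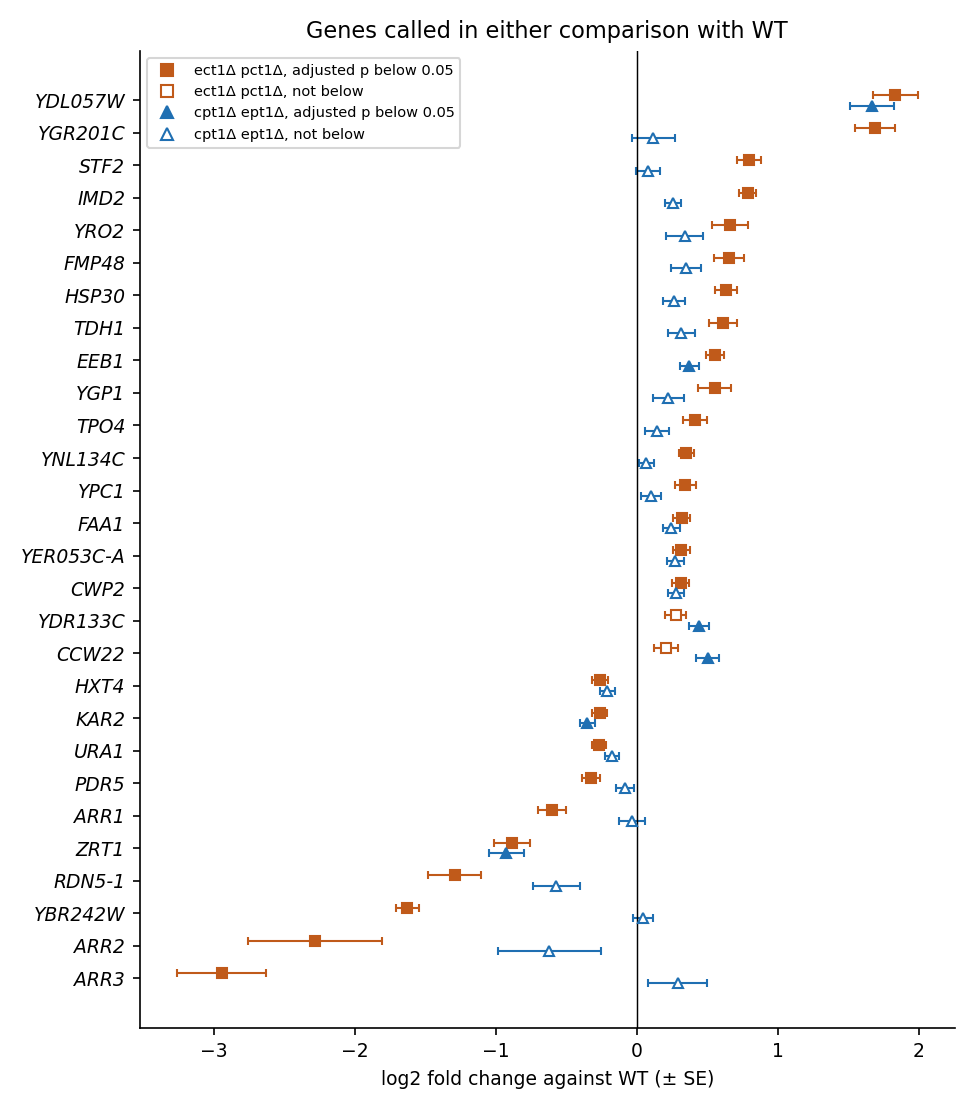
Log2 fold change against WT (± SE, 3 libraries per group) of the 28 genes called in either comparison with WT, the deleted genes left out; squares are ect1Δ pct1Δ, triangles are cpt1Δ ept1Δ, and filled symbols have an edgeR Benjamini-Hochberg adjusted p below 0.05. YDL057W, EEB1, ZRT1 and KAR2 are filled for both strains, and ARR3 and ARR2 lie lowest in ect1Δ pct1Δ at -2.94 and -2.28.

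**Figure D3:**
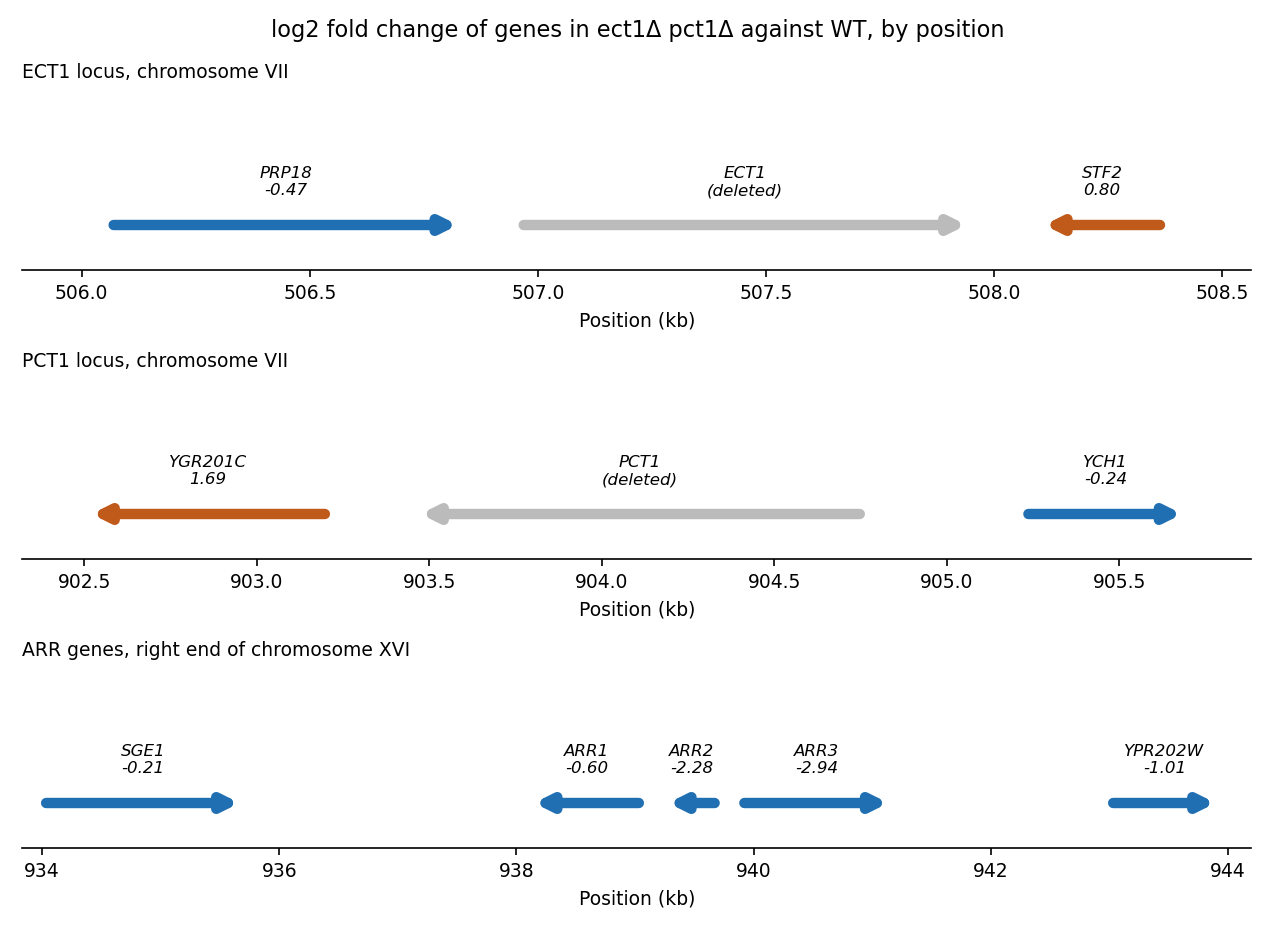
Positions (kb, build R64) of the genes around ECT1 and PCT1 on chromosome VII and of the ARR genes on chromosome XVI. Arrows show gene extent and strand. The number at each gene is its log2 fold change in ect1Δ pct1Δ against WT (orange higher, blue lower, grey deleted). STF2 (0.80) and YGR201C (1.69) lie 169 and 276 bases from the deleted genes, and ARR1, ARR2 and ARR3 are adjacent.

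Among the gene lists fixed before the data were examined, respiratory genes were higher in ect1Δ pct1Δ, and ergosterol genes and targets of the unfolded protein response were lower, by small amounts. All 35 measured genes of oxidative phosphorylation, the respiratory chain and ATP synthase, had positive log2 fold changes, with a median of 0.16. Examples are the Rieske protein gene RIP1 (0.20 ± 0.05), and ATP16 and ATP20 of the ATP synthase (0.21 ± 0.06 and 0.28 ± 0.08), none of which was called by itself. The list mean was 0.15 ± 0.04 above the WT mean of 0.00 ± 0.03 on the log2 scale (SD, n = 3 libraries). By edgeR over all genes 0 members passed, 16 passed when adjusted over the list alone, and 25 had an unadjusted p below 0.05. The list passed camera with Benjamini-Hochberg adjustment over 42 lists (adjusted p = 1.05e-20), but not with the correlation between genes estimated (adjusted p = 0.0756 with an estimated correlation). Genes of the tricarboxylic acid cycle had a median of 0.07, with 15 of 20 positive, 0 called by edgeR over all genes, 4 when adjusted over the list alone and 7 at an unadjusted p below 0.05, CIT1 (0.26), SDH2 (0.24) and MDH1 (0.18) among the largest. Its camera Benjamini-Hochberg adjusted p was 9.45e-04 (adjusted p = 0.429 with an estimated correlation). Among the lists that passed camera in the 3 comparisons, those with no member called by edgeR over all genes had none called by DESeq2 either.

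Ergosterol synthesis genes were lower in 26 of 27 cases, with a median log2 fold change of -0.10, ERG3, MVD1 and ERG26 at -0.14 each among them. By edgeR 0 of them passed over all genes, 0 passed when adjusted over the list alone and 5 had an unadjusted p below 0.05; camera's Benjamini-Hochberg adjusted p was 4.84e-07 (adjusted p = 0.0756 with an estimated correlation). Targets of the unfolded protein response were lower in 18 of 22 cases, with a median of -0.08. KAR2 fell among them, over all genes and when adjusted over the list alone (1 gene in each case), and EUG1 and ERO1, which help form disulfide bonds, stood at -0.24 and -0.16. Camera's Benjamini-Hochberg adjusted p was 9.80e-05 (adjusted p = 0.0756 with an estimated correlation). With the estimated correlation 0 of 42 lists passed, and with fry, which asks whether a list's genes move one way on balance, 5 did.

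General stress genes (targets of Msn2) were higher in 29 of 33 cases, with a median of 0.20 and DDR2 (0.68 ± 0.19), YGP1 (0.55 ± 0.11) and PNC1 (0.25 ± 0.09) as examples. Of these YGP1 was called by edgeR over all genes, and 2 genes were called when adjusted over the list alone; camera's Benjamini-Hochberg adjusted p was 1.80e-06 (adjusted p = 0.212 with an estimated correlation). Markers of stationary-phase cells, kept as a sign of cultures past log phase, were positive in 13 of 15 cases, with a median of 0.21 and 1 gene called both over all genes and when adjusted over the list alone. That gene is STF2, the neighbour of ECT1; HSP26 (0.30) and HSP12 (0.59) were not called. The list's camera Benjamini-Hochberg adjusted p was 7.67e-04 (adjusted p = 0.0756 with an estimated correlation), and 0.114 once the genes next to deleted loci were removed from it, an alternative chosen after the data were seen. Cell cycle and histone genes (median 0.05, 23 of 27 positive, 0 called by edgeR over all genes and 3 when adjusted over the list alone, 7 at an unadjusted p below 0.05) passed camera with a Benjamini-Hochberg adjusted p of 9.45e-04 (adjusted p = 0.146 with an estimated correlation). Glutathione and redox genes (median 0.08, 19 of 25 positive, 4 at an unadjusted p below 0.05) and ribosome biogenesis genes (median -0.04, 31 of 43 negative, 0 at an unadjusted p below 0.05) had 0 called by edgeR over all genes or when adjusted over the list alone. Camera's Benjamini-Hochberg adjusted p-values were 0.0339 (adjusted p = 0.477 with an estimated correlation) and 0.0451 (adjusted p = 0.777 with an estimated correlation), and both calls ended without WT replicate 1 or without ect1Δ pct1Δ replicate 2 (up to 0.194 and 0.619). The glutathione call also ended without WT replicate 2, and the ribosome biogenesis call without WT replicate 3, ect1Δ pct1Δ replicate 1 or cpt1Δ ept1Δ replicate 3. The length and GC correction and fry ended both calls, and limma on FPKM, the replicate block and removal of the genes next to deleted loci ended the ribosome biogenesis call, which was lost in 12 of 17 alternatives (Benjamini-Hochberg adjusted p up to 0.777). The other 33 lists had camera Benjamini-Hochberg adjusted p-values of 0.0571 to 0.903.

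The rest of phosphatidylethanolamine and phosphatidylcholine synthesis was not detectably different in ect1Δ pct1Δ. The log2 fold changes were 0.05 ± 0.07 for CHO1, the phosphatidylserine synthase gene, -0.03 ± 0.07 and -0.10 ± 0.07 for the decarboxylase genes PSD1 and PSD2, and 0.00 ± 0.06 and 0.09 ± 0.07 for the methyltransferase genes CHO2 and OPI3. SAM1 and SAM2, which make the methyl donor S-adenosylmethionine, stood at -0.08 and -0.03. INO1, the inositol-3-phosphate synthase gene and a main target of the Ino2 activator and the Opi1 repressor, was at -0.30 ± 0.19 (edgeR, Benjamini-Hochberg adjusted p = 0.884), and the genes OPI1 and INO2 at 0.11 and -0.04. The 13 measured genes of the CDP-diacylglycerol route had a median of 0.05 and the 21 Ino2/Ino4 targets a median of -0.02, with camera Benjamini-Hochberg adjusted p-values of 0.662 and 0.842. The 3 remaining genes of the CDP-choline and CDP-ethanolamine route had a median of -0.02, with a camera Benjamini-Hochberg adjusted p of 0.6. In data simulated from these libraries for this comparison (6057 genes), edgeR recovered 38.8% of the genes given the smallest simulated change and 80% of those changed 1.5-fold. The simulation made 154 calls against 28 here, so its threshold on unadjusted p was looser and these shares are likely too high. Changes of these sizes and smaller can thus have been missed.

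**Figure D4:**
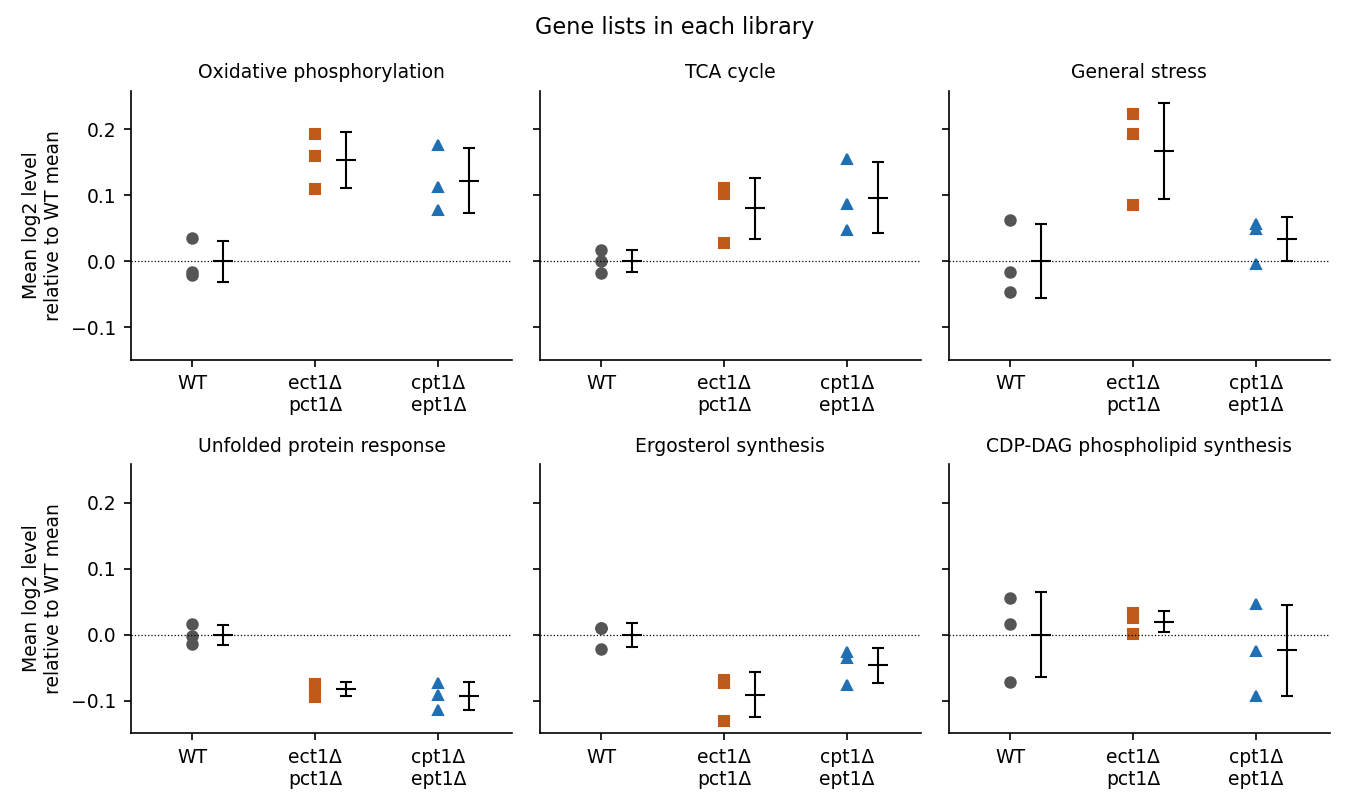
Mean log2 level per library of 6 gene lists relative to the WT mean, with points for libraries and bars for the group mean ± SD (n = 3). Oxidative phosphorylation lies at 0.15 in ect1Δ pct1Δ and 0.12 in cpt1Δ ept1Δ, the unfolded protein response at -0.08 and -0.09, and the CDP-diacylglycerol route at 0.02 and -0.02.

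The comparison of cpt1Δ ept1Δ with WT asks the same question for the last step of the route. Fewer genes were called here, which does not show that fewer changed. YDL057W rose 3.19-fold, from 5.86 ± 1.5 to 19.0 ± 0.541 CPM, ZRT1 fell to 52.7% of WT (43.2 ± 11.2 CPM), KAR2 fell to 78.5% (from 650 ± 17.2 to 510 ± 18.3 CPM), and EEB1 rose 1.30-fold (from 544 ± 29.3 to 705 ± 48.5 CPM). CCW22 (YDR134C, chromosome IV, 721071 to 721481) rose 1.42-fold together with YDR133C, which overlaps it, so that their reads cannot be told apart.

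By edgeR with Benjamini-Hochberg adjustment, 8 of 6083 genes passed, the 2 deleted genes included; of the 6 others 4 were higher and 2 lower, and 1 differed by at least 2-fold. In these 6 the libraries of both groups did not overlap, against 10.4% of all tested genes and 10% by chance; 321 genes had an unadjusted p below 0.05, against 304 expected. The log2 fold changes were 1.67 ± 0.16 for YDL057W, -0.92 ± 0.12 for ZRT1, -0.35 ± 0.05 for KAR2, 0.50 ± 0.08 for CCW22, 0.44 ± 0.07 for YDR133C and 0.37 ± 0.06 for EEB1. Their edgeR Benjamini-Hochberg adjusted p-values were 9.40e-06, 0.00129, 0.00499, 0.0114, 0.00890 and 0.0155; YDL057W and YDR133C, which have no other symbol, are named after their values were seen. The calls ended without cpt1Δ ept1Δ replicate 2 for KAR2, EEB1 and CCW22, without WT replicate 1 or cpt1Δ ept1Δ replicate 3 for EEB1, and without WT replicate 2 or cpt1Δ ept1Δ replicate 1 for CCW22, with edgeR Benjamini-Hochberg adjusted p up to 0.0815, 0.139 and 0.0844 for the 3 genes. CCW22 was not called by limma on FPKM in any of 4 settings (Benjamini-Hochberg adjusted p up to 0.364). Without cpt1Δ ept1Δ replicate 2 the total was 4 genes, and DESeq2 with its own size factors gave 17. In data simulated for this comparison 11.0% of the edgeR calls were false, more than the 5% aimed at.

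Respiratory genes were higher and targets of the unfolded protein response lower in cpt1Δ ept1Δ too. Of the 35 oxidative phosphorylation genes 34 had positive log2 fold changes, with a median of 0.11 and RIP1 (0.16 ± 0.05), COR1 (0.16 ± 0.05) and SDH4 (0.26 ± 0.08) as examples. By edgeR 0 passed over all genes, 0 passed when adjusted over the list alone and 11 had an unadjusted p below 0.05; camera's Benjamini-Hochberg adjusted p was 2.68e-14 (adjusted p = 0.179 with an estimated correlation). Tricarboxylic acid cycle genes had a median of 0.09, with 17 of 20 positive, 0 called by edgeR over all genes, 5 when adjusted over the list alone and 9 at an unadjusted p below 0.05, among the largest the isocitrate dehydrogenase genes IDH1 and IDH2 (0.19 each). The camera Benjamini-Hochberg adjusted p of this list was 4.12e-07 (adjusted p = 0.275 with an estimated correlation). Markers of stationary-phase cells were positive in 11 of 15 cases, with a median of 0.06, and their mean of 0.11 ± 0.02 lay apart from that of WT (0.00 ± 0.02, SD, n = 3 libraries) in all libraries, but the list did not pass camera (Benjamini-Hochberg adjusted p = 0.135, and 0.0427 to 0.407 over its alternatives). Targets of the unfolded protein response were lower in 19 of 22 cases, with a median of -0.09. KAR2 fell over all genes, 2 genes were called when adjusted over the list alone, and HAC1, the transcription factor of this response, stood at -0.24 ± 0.05 (edgeR, Benjamini-Hochberg adjusted p = 0.122), with reads that it may share with overlapping genes. This list passed camera with Benjamini-Hochberg adjustment (adjusted p = 1.95e-06), also with the correlation estimated (adjusted p = 0.0485 with an estimated correlation) and with fry (Benjamini-Hochberg adjusted p = 0.00280), as no other list did in this comparison.

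Nitrogen catabolite genes, which serve the use of poor nitrogen sources, were lower in 19 of 28 cases with a median of -0.06, CPS1 (-0.24 ± 0.06) and the allantoate permease gene DAL5 (-0.29 ± 0.10) being examples. By edgeR 0 passed over all genes and 1 when adjusted over the list alone, with 7 at an unadjusted p below 0.05; camera's Benjamini-Hochberg adjusted p was 0.00191 (adjusted p = 0.407 with an estimated correlation), and 0.0622 without WT replicate 1. Targets of the mitochondrial retrograde response, which include CIT1, IDH1 and IDH2, had a median of 0.05, with 11 of 14 positive, 0 called by edgeR over all genes, 3 when adjusted over the list alone and 5 at an unadjusted p below 0.05. Ergosterol genes were lower in 23 of 27 cases, with a median of -0.04, 0 called over all genes or when adjusted over the list alone and 2 at an unadjusted p below 0.05 by edgeR, NCP1 (-0.12) and ERG1 (-0.11). The camera Benjamini-Hochberg adjusted p-values of these lists were 0.00223 and 0.0147 (adjusted p = 0.407 with an estimated correlation for each). Both calls ended without a single library, at up to 0.190 without WT replicate 3 for the retrograde targets, which cpt1Δ ept1Δ replicate 1 also decided, and up to 0.173 without cpt1Δ ept1Δ replicate 2 for ergosterol, which WT replicate 1 also decided.

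The rest of phosphatidylethanolamine and phosphatidylcholine synthesis was not called by edgeR over all genes in cpt1Δ ept1Δ either. CHO1, PSD1, CHO2 and OPI3 had log2 fold changes of 0.02, -0.02, -0.01 and -0.02, and INO1 one of -0.18 ± 0.19. The medians were -0.01 for the CDP-diacylglycerol route and -0.02 for the Ino2/Ino4 targets, with camera Benjamini-Hochberg adjusted p-values of 0.739 and 0.599. The 3 remaining genes of the CDP-choline and CDP-ethanolamine route had a median of 0.01 and a camera Benjamini-Hochberg adjusted p of 0.597, with 1 gene lower when adjusted over the list alone. In simulated data for this comparison (6067 genes), edgeR recovered 59.2% of the genes given the smallest simulated change and 76.0% of those changed 1.5-fold. The simulation made 182 calls against 8 here, so its threshold on unadjusted p was looser and these shares are likely too high.

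The direct comparison of cpt1Δ ept1Δ with ect1Δ pct1Δ asks whether loss of the last step differs from loss of the step before it. ARR3, ARR1 and a few other genes set the strains apart, while ARR2 (log2 difference of 1.66 ± 0.49) was not called (edgeR, Benjamini-Hochberg adjusted p = 0.456). ARR3 was 9.41-fold higher in cpt1Δ ept1Δ (7.69 ± 0.952 against 0.873 ± 0.454 CPM), YBR242W 3.18-fold higher (88.0 ± 2.52 against 28.1 ± 2.90 CPM) and ARR1 1.48-fold higher. YGR201C, IMD2, STF2 and IRC7, a cysteine desulfhydrase gene, were lower, at 33.7%, 69.2%, 60.7% and 69.2% of the level in ect1Δ pct1Δ. By edgeR with Benjamini-Hochberg adjustment 12 of 6083 genes passed, the 4 deleted genes included, and of the 8 others 3 were higher, 5 lower and 3 different by at least 2-fold. All 8 had libraries that did not overlap, against 10.3% of all tested genes and 10% by chance, and 287 genes had an unadjusted p below 0.05, against 304 expected.

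The log2 fold changes between the strains were 3.23 ± 0.30 for ARR3, 1.67 ± 0.08 for YBR242W, 0.57 ± 0.10 for ARR1, -1.57 ± 0.14 for YGR201C, -0.72 ± 0.08 for STF2, -0.53 ± 0.06 for IMD2 and -0.53 ± 0.08 for IRC7. The edgeR Benjamini-Hochberg adjusted p-values of ARR3, ARR1, STF2, IMD2 and IRC7 were 3.65e-06, 0.00971, 6.05e-05, 2.25e-05 and 0.00131. IRC7 overlaps YFR056C, so its reads are uncertain, and by limma without a trend it was not called (Benjamini-Hochberg adjusted p = 0.0967). The eighth gene, YNL134C, named with YBR242W and YGR201C after the values were seen, had a log2 fold change of -0.29 with an edgeR Benjamini-Hochberg adjusted p of 0.0237. The ARR1 call ended without ect1Δ pct1Δ replicate 1 or 3 or cpt1Δ ept1Δ replicate 1 or 3, with an edgeR Benjamini-Hochberg adjusted p of up to 0.0895.

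General stress genes were lower in cpt1Δ ept1Δ than in ect1Δ pct1Δ in 26 of 33 cases, with a median of -0.16, SPI1 (-0.52 ± 0.14), YGP1 (-0.33 ± 0.11) and HOR7 (-0.22 ± 0.06) among them. By edgeR 0 passed over all genes, 2 passed when adjusted over the list alone and 7 had an unadjusted p below 0.05; camera's Benjamini-Hochberg adjusted p was 2.18e-05 (adjusted p = 0.377 with an estimated correlation). Stationary-phase markers moved the same way, with a median of -0.12 and list means of 0.11 against 0.20 with libraries apart, without passing camera (Benjamini-Hochberg adjusted p = 0.0858). These means include STF2, the neighbour of ECT1, at -0.72 between the strains, so part of the gap comes from that gene. Whether the libraries stay apart without STF2 was not tested. A different state of the cultures is not excluded. Nitrogen catabolite genes were lower in 22 of 28 cases, with a median of -0.09, with the urea permease gene DUR3 (-0.64 ± 0.17) and the proline oxidase gene PUT1 (-0.35 ± 0.10) as examples. Both differences are enlarged by ect1Δ pct1Δ replicate 1, with 32.8 CPM of DUR3 against 19.1 and 20.1 in the other replicates and 138 CPM of PUT1 against 98.9 and 107. Those other replicates still lay above the cpt1Δ ept1Δ libraries, at 13.5 to 16.2 CPM of DUR3 and 87.4 to 92.9 CPM of PUT1. Here 0 passed over all genes by edgeR, 2 when adjusted over the list alone and 7 at an unadjusted p below 0.05; camera's Benjamini-Hochberg adjusted p was 1.55e-04 (adjusted p = 0.377 with an estimated correlation). The unfolded protein response list did not separate the strains, with a median of 0.00 and a camera Benjamini-Hochberg adjusted p of 0.959.

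Further lists passed camera between the strains. Amino acid synthesis genes under Gcn4 were higher in 37 of 49 cases (median 0.03, LEU1 at 0.16, LEU4 at 0.14 and ILV5 at 0.12) and ergosterol genes in 24 of 27 (median 0.04, ERG28 at 0.14). Cell cycle and histone genes were lower in 22 of 27 cases (median -0.07, CLN1 at -0.19), oxidative phosphorylation genes in 29 of 35 (median -0.05, COX8 at -0.13) and sporulation markers in 16 of 18 (median -0.11). Of these lists 0 members were called by edgeR over all genes, 1 sporulation marker was called when adjusted over the list alone, and 3, 0, 3, 1 and 2 members in the order given had an unadjusted p below 0.05. The camera Benjamini-Hochberg adjusted p-values were 0.00170 for Gcn4 targets (adjusted p = 0.730 with an estimated correlation), 0.0102 for ergosterol, 0.00909 for cell cycle and 0.0305 for sporulation (adjusted p = 0.377 with an estimated correlation for each), and 0.0234 for oxidative phosphorylation (adjusted p = 0.830 with an estimated correlation). All 5 calls ended when single libraries were left out, at up to 0.115, 0.195, 0.111, 0.132 and 0.464, and leaving out any of the 6 libraries compared ended at least 1 of them. All 5 also ended with fry, the sporulation call with limma on FPKM and the oxidative phosphorylation call with median centring or the length and GC correction. Without ect1Δ pct1Δ replicate 1 the number of lists called was 3, and without cpt1Δ ept1Δ replicate 3 it was 4, in place of 7.

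Both double deletions shared 4 calls against WT in the same direction: YDL057W and EEB1 were higher, ZRT1 and KAR2 lower, with log2 fold changes of 1.84 and 1.67 for YDL057W, 0.56 and 0.37 for EEB1, -0.88 and -0.92 for ZRT1 and -0.26 and -0.35 for KAR2 in ect1Δ pct1Δ and cpt1Δ ept1Δ. No gene was called in opposite directions. Over 6079 genes, independent lists of these sizes would share 0.0105 genes higher and 0.00329 lower, against 2 and 2 observed. Unchanged groups simulated with a shared WT group (100 simulations) shared 0.05 and 0.04 on average. They had only 0.42 and 0.58 calls on average, against 26 and 6 here, so their overlap is no baseline for lists of the real sizes. The figures for independent lists leave out the shared WT group, which can itself produce shared calls. All libraries, WT included, were drawn anew there, so features of the real WT libraries are not covered. Without WT replicate 1, or without cpt1Δ ept1Δ replicate 2, 2 shared calls were left. EEB1 in cpt1Δ ept1Δ was also not called by limma on FPKM in any of 4 settings or with the replicate block (adjusted p up to 0.344 with Benjamini-Hochberg). KAR2 in ect1Δ pct1Δ was not called with median centring, the replicate block, only the 6 libraries compared or limma without a trend (Benjamini-Hochberg adjusted p up to 0.189). By limma without a trend ZRT1 was called in neither strain (Benjamini-Hochberg adjusted p = 0.190 and 0.237) and KAR2 not in cpt1Δ ept1Δ (0.0867). The covariance of the log2 fold changes of the strains across genes was 0.0147, against 0.0113 (0.00998 to 0.0131) in the simulations, a difference of 0.00343, and their correlation was 0.511 against 0.519. The 3 WT libraries cannot be split into parts of 2, so part of the excess may come from the shared controls.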

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

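The tests of genes next to deleted loci, of an equal fold across the ARR genes, of glucose exhaustion and of other splits for gene counts were chosen after the result was seen, and those of chromosome ends, near-identical copies, gene length and GC content and other splits for gene lists were chosen once the patterns had been found in these data but before their own values were computed.

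Some effects differed between the double deletions by the test of the difference itself (edgeR or camera with Benjamini-Hochberg adjustment), given here as cpt1Δ ept1Δ minus ect1Δ pct1Δ on the log2 scale. The deleted genes differed by -9.50 for CPT1, 7.17 for PCT1, -9.73 for EPT1 and 9.57 for ECT1, fitted values that rest on 0 to 11 counts per library in the strain that lacks the gene and depend on edgeR's prior. IMD2 differed by -0.53, IRC7 by -0.53, YNL134C by -0.29 and YBR242W by 1.67. The list medians differed by -0.16 for general stress genes, -0.0941 for nitrogen catabolite genes, 0.0321 for amino acid genes under Gcn4, -0.0653 for cell cycle and histone genes, 0.0411 for ergosterol genes, -0.0500 for oxidative phosphorylation genes and -0.11 for sporulation markers. None of these 7 lists passed with an estimated correlation between genes (adjusted p of 0.377 to 0.830 with an estimated correlation) or with fry. NDT80, the neighbour of EPT1, is a sporulation marker, and this list no longer passed without the genes next to deleted loci (camera, Benjamini-Hochberg adjusted p = 0.179).

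STF2 and YGR201C, which differed by -0.72 and -1.57 between the strains, lie 169 and 276 bases from the deleted ECT1 and PCT1. The tables argue against a response to the loss of the shared pathway as their cause, since the strain lacking its last step held both genes near WT (log2 fold changes of 0.08 and 0.12). Both were called in the difference (edgeR, Benjamini-Hochberg adjusted p of at most 6.05e-05), the test that flagged them, so that call adds no separate support. A local effect of the replaced locus on its neighbour may account for them. The other genes adjacent to deleted loci, PRP18, YCH1, TOM22, DGR1, CIA2 and NDT80, were not called, but 5 of these 6 had an unadjusted p below 0.05 (4 lower and 1 higher), against 5.86% of 12150 other tests, with a two-sided Fisher's exact p of 4.02e-06 in a test chosen with their values known. A response to the loss of ECT1 and PCT1 alone stays open, as no strain with the same genes lost in another way was analysed here.

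ARR3 differed by 3.23 and ARR1 by 0.57 between the strains, and with ARR2 they were lower in ect1Δ pct1Δ than in WT. A gap between ARR1 and ARR3 of 7.03 combined standard errors argues against an equal fold across these genes. It cannot settle whether 1 copy of the whole segment was lost, since a lower level of Arr1 could lower ARR3 beyond the copy loss. A general lowering near chromosome ends is argued against by 169 other genes within 20 kb of an end. Their median log2 fold change was 0.00 (0.00464, 95% bootstrap interval -0.0278 to 0.0308). Reads shared with a near-identical copy elsewhere in the reference are argued against by 0 such matches. A lower level of the activator Arr1 may have lowered ARR2 and ARR3 further, but this was not tested, and a change in or beside the locus that arose in this strain alone stays open as well. The genes between ARR3 and the chromosome end, YPR202W, YPR203W and YPR204W, had log2 fold changes of -1.01, -1.15 and -0.13 and were not called.

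Oxidative phosphorylation genes were higher than WT in both double deletions, with medians of 0.16 and 0.11. Over all genes the log2 fold change fell with exonic length, with Spearman correlations of -0.203 in ect1Δ pct1Δ and -0.154 in cpt1Δ ept1Δ. The genes of this list are short, with a median of 483 bases against 1152 for all tested genes, so length may account for part of the rise. A bias by gene length or GC content is argued against as the whole cause. The correction kept at least 78.7% of the median in each comparison, and the list still passed camera (Benjamini-Hochberg adjusted p = 6.34e-17 and 1.23e-11). A harvest closer to glucose exhaustion cannot be told apart from an effect of the deletions: the median of 21 glucose-repressed genes minus that of the list was -0.03 in ect1Δ pct1Δ (-0.0294, 95% bootstrap interval -0.218 to 0.0265) and -0.07 in cpt1Δ ept1Δ (-0.122 to 0.0794), and both intervals include 0. Stationary-phase markers, with list means of 0.20 and 0.11 against 0.00 in WT and libraries apart in both strains, moved the way such a harvest would move them. The mean of 0.20 includes STF2, the neighbour of ECT1, with a log2 fold change of 0.80. Without genes next to deleted loci this list did not pass camera in ect1Δ pct1Δ (Benjamini-Hochberg adjusted p = 0.114). RDN5-1, nearly all of the residual nuclear ribosomal RNA, also separated the groups. Mitochondrial ribosomal RNA and SCR1, the RNA of the signal recognition particle, overlapped between them. A difference in RNA or poly(A) selection between the groups was not tested. An effect of the blocked phospholipid route on respiratory genes stays open and was not tested. With an estimated correlation between genes the list did not pass in either comparison (adjusted p = 0.0756 and 0.179 with an estimated correlation).

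Other splits of the 6 libraries into 3 and 3 are too few, at 10 per comparison, to give a share below 0.05. For genes, the real split gave 28 calls and the highest other split 16 for ect1Δ pct1Δ against WT, 8 and 1 for cpt1Δ ept1Δ against WT, and 12 and 0 between the strains. Thus 1 split, the real one, reached its count in each comparison. The real counts include 2, 2 and 4 deleted genes, which only the real split sets apart by construction. Without these the real split gave 26, 6 and 8 calls. For gene lists, the real split gave 9 calls and the highest other 8 for ect1Δ pct1Δ against WT, 6 and 7 for cpt1Δ ept1Δ against WT, and 7 and 9 between the strains, and 1, 7 and 5 splits reached the real count.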

How the results depend on the processing

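The corrections for length and GC content, total counts alone, limma with a pseudocount of 1 and a trend, lists without neighbours of deleted loci and the limit of 20 CPM were tests chosen after the data were seen. Through the alternatives, single called genes were followed if named by the rule for that comparison, together with YBR242W, YDL057W and YGR201C. The other calls, among them EEB1 in ect1Δ pct1Δ, RDN5-1, YDR133C and YNL134C, were not followed singly. No followed gene and no called list reversed its direction under any alternative. Of 441 values of followed genes, the deleted genes included, under alternatives that kept all libraries, 396 stayed called and 45 were no longer past the threshold. With a library left out, 297 of 333 stayed called and 36 did not. For ect1Δ pct1Δ against WT (28 genes), a fold of at least 2 left 8 genes, limma without a trend gave 13, and the other alternatives 20 to 34; leaving out single libraries gave 17 (without WT replicate 1) to 40 (without WT replicate 3). For cpt1Δ ept1Δ against WT (8 genes), a fold of at least 2 left 3, limma without a trend gave 5, the length and GC correction 16 and DESeq2 17, and single libraries left out gave 4 (without cpt1Δ ept1Δ replicate 2) to 9 (without ect1Δ pct1Δ replicate 2). Between the strains (12 genes), a fold of at least 2 left 7 and single libraries left out gave 10 to 13. Of the shared calls (4), 1 had a fold of at least 2, 3 lay among genes of at least 20 CPM, and 2 to 4 were left without single libraries (2 without WT replicate 1 or without cpt1Δ ept1Δ replicate 2). Lists called were 9, 6 and 7 in these comparisons, 0, 1 and 0 with an estimated correlation and 5, 1 and 0 with fry; without single libraries they were 8 to 10, 5 to 10 (10 without WT replicate 3 or without cpt1Δ ept1Δ replicate 3) and 3 to 8 (3 without ect1Δ pct1Δ replicate 1, 4 without cpt1Δ ept1Δ replicate 3), and 7, 6 and 6 without the neighbours. The fold limit removes genes by construction; for the other differences the cause was not tested. With the replicate number as a block, 23, 7 and 11 genes and 8, 7 and 8 lists were called. The numbers do not pair the libraries: deviations of same-numbered libraries correlated between -0.268 and 0.264, and not every library correlated best with its own number. TMM factors on the values, planned as an alternative, are part of the main test and give no separate value.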

Other observations

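Of the 17 measured genes of the zinc regulon ZRT1 alone was called in each double deletion. The list had medians of 0.01 and -0.01, with members on both sides of 0, and camera Benjamini-Hochberg adjusted p-values of 0.418 and 0.264. The log2 difference of ZRT1 between the strains was -0.04 ± 0.13.

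Residual RNA without poly(A) tails differed between libraries. Nuclear ribosomal RNA, nearly all of it the called gene RDN5-1, also differed between groups, while mitochondrial ribosomal RNA and SCR1 overlapped between them. Mitochondrial ribosomal RNA took 191 CPM in cpt1Δ ept1Δ replicate 3 and 2.37 to 34.4 CPM in the other libraries. SCR1, the RNA of the signal recognition particle, ranged from 1.10 to 40.1 CPM. Ribosomal RNA genes of the nucleus took 10.1, 13.6 and 11.4 CPM in the WT libraries, 4.26, 5.0 and 4.94 in ect1Δ pct1Δ and 7.30, 7.38 and 8.84 in cpt1Δ ept1Δ.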
